A study of Mus musculus with 57 samples.

How the data were processed

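The series measured chromatin in mouse EpiSCs and embryos by ChIP-seq, ATAC-seq and 4C-seq. The 32 samples with a deposited list of peaks were used (23 ChIP-seq, 2 input and 7 ATAC-seq libraries), and the other 25 samples, of 4C-seq, were not analysed here. Each file was a list of the peaks of 1 library in mm9 coordinates.

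The submitters' processing notes name Bowtie 1.1.0, SAMtools 0.1.19 and MACS2 2.1.0 for ChIP-seq, and cutadapt 1.8.1, Bowtie2 2.1.0, SAMtools 0.1.19 and MACS2 2.1.0 for ATAC-seq, without the role or order of each, and give mm9 as the build. The peak lists have the narrowPeak layout that MACS2 writes. The library used as background in peak calling is not given in the sources used here. For 4 wild-type ChIP-seq samples (both H3K27ac libraries at 24 h and a pair of H3K4me3 libraries) the tools are not given in the sources used here. Settings in the peak names in the files were read as an extension of ChIP-seq reads to 300 bp and a local background of 100 kb. The names also show that the lists came from 7 processing folders of 8, 6, 1, 4, 6, 4 and 3 lists, which were treated as batches. In the deposited lists the fold enrichment is, per the file format, the ratio of signal over local background at the peak summit that the authors' peak caller gave. The deposited −log10 p and −log10 q values came from the authors' peak caller as well, the second after its correction for multiple tests, and the lowest −log10 p in any list was 5.00. The deposited score, from the authors' peak caller, is 10 times the −log10 p value rounded down, as checked on the files, and it was not used. The fold enrichment served only to order regions within a list, and no value was compared between lists.

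The lists hold no read counts, so depth is unknown, and no limit can be set for regions that are absent, which may be missed at low depth. Peaks of a list that overlapped were merged into regions, which removed no region in any list. In all, 60.8% to 100.0% of the peaks of a list had a −log10 q of at least 5. Regions of different lists were called overlapping when they shared at least 1 bp. Shares carry 95% Wilson intervals and region counts 95% exact Poisson intervals, which cover counting error only. Chance overlap was measured with 1000 circular shifts of the regions along each chromosome (100 for the ATAC-seq classes). The p-value for embryonic stages comes from an exact two-sided permutation test of the libraries. With 1 library per group no test was run, and a difference was set against the SD of the nearest pair of replicates or, for H3K4me3, against the Poisson interval. For the difference between the ends of the clusters, the SD of that difference between replicates was used (H3K27ac at 24 h, or E6.0 for ATAC-seq). For H3K4me3 the Poisson errors of all counts that enter a difference were combined.

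The windows of the 4 Hox clusters (115 kb for HoxA, 187 kb for HoxB, 127 kb for HoxC and 106 kb for HoxD) were placed in mm9 from knowledge of the genome, since the gene table at hand is of another assembly. They were checked by the coverage of Ring1b at 0 h, which lay at percentiles 99.3 to 100.0 of 10000 random windows. H3K27me3 at 0 h, also set for this check, lay at percentiles 0 (HoxC) to 97.5 in the first replicate and 88.9 (HoxC) to 99.0 in the second, so the check rests on Ring1b. That gene table, of GRCm38, was used only for names and the orientation of the clusters. The comparison of the flanks of HoxA is not reported here. ATAC-seq classes were defined in wild-type EpiSCs as regions listed at 48 h and not at 0 h, at both times, or at 0 h and not at 48 h. Gained and lost regions of the other marks were defined the same way, and Polycomb regions at 0 h were those of the first replicate that overlapped the second. The regions named in the text are those with the highest fold enrichment, by the authors' values, among the 10 leading gained or lost regions of a comparison, a rule for files without an mm9 annotation. The examples taken from ATAC-seq were picked after their values were seen. Regions within 100 kb of an input region were marked, a distance set after a first table had been seen.

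Groups were taken from the labels. The stage names inside the peak names of the embryo lists differ from the labels, and the labels were followed. A pair of wild-type H3K4me3 libraries has labels that contradict each other about stimulation, so they were left out of every comparison. Replicate numbers were not taken to pair libraries, since the labels give no shared litter, day or culture.

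The comparisons, windows, overlap rule and alternatives were chosen before the data were examined. The alternatives were an overlap of at least 50% of the smaller region, a −log10 q of at least 5, merging of regions within 1 kb (for region counts and covered length), lists of equal length (the strongest regions of each list, up to the length of the shortest list of that mark), Hox windows 20 kb longer on each side, leaving out each replicate (for Hox coverage, not of the embryo libraries), and a replicate block for the embryonic stages. Chosen after seeing the data were the split of the clusters into 3 equal parts, the scan of 100 kb tiles, the alternative without regions that overlap an input region, the crossed pairing of the embryo libraries, leaving out each embryo library for Hox coverage, lists of equal length for H3K27ac at ATAC-seq classes and for the tiles, and the choice of the latest time points as the main results. Marks at the promoters of listed genes, peaks near listed genes, markers of cell types and motifs in gained regions were not analysed here, as they need a genome or gene positions of mm9. Computation used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated lists made from 3 real ones (41309 ATAC-seq, 1605 Ring1b and 12135 H3K27ac regions) with 20%, 50% or 80% of regions drawn to be shared, and the share found differed from the true one by 0 points each time.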

Results

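Chromatin was profiled in mouse epiblast stem cells (EpiSCs), cell lines derived from the epiblast that resemble the embryo shortly before gastrulation, and in early mouse embryos. The cells were kept with IWP2, an inhibitor that blocks Wnt secretion, and were then stimulated with CHIR99021 (3 µM), which activates the Wnt pathway inside the cell by inhibiting GSK3, or with Wnt3a protein (125 ng/mL). Of the 57 samples of the series, the 32 with a list of peaks were analysed, which were 23 ChIP-seq libraries with an antibody, 2 input libraries without one and 7 ATAC-seq libraries. ChIP-seq was done for H3K4me3 (a mark of promoters), H3K27ac (a mark of active promoters and enhancers), H3K27me3 (the mark set by Polycomb repressive complex 2) and Ring1b (a subunit of Polycomb repressive complex 1), and ATAC-seq lists open chromatin. The ChIP-seq time course was run in EpiSCs lacking Wnt3 (Wnt3 KO), and H3K27ac was also measured in wild-type EpiSCs. A pair of wild-type H3K4me3 libraries had contradictory labels and entered no comparison. ATAC-seq was done only in wild-type EpiSCs and wild-type embryos. Embryos were taken at embryonic day 6.0 (E6.0), at E7.2 and, as posterior parts, at E7.5. Groups with 2 libraries were H3K27ac in wild-type cells at 24 h, H3K27me3 and Ring1b at 0 h, and ATAC-seq at E6.0 and at E7.2, and the other 20 groups had 1 library and no replicate error. The labels do not say that paired libraries came from separate cultures or litters, so spreads and p-values may be technical.

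The lists carry no read totals, so the depth of each library is unknown. The number of regions is given instead, but it does not measure depth by itself. H3K4me3 lists of the time course held 16287 to 17714 regions, H3K27ac lists 10161 to 12135 in Wnt3 KO cells, and 14453 (0 h), 29056 and 27422 (24 h) in wild-type cells. H3K27me3 lists ranged from 1012 (Wnt3a, 5 h) to 6236 regions, Ring1b lists from 604 (72 h) to 2244, and ATAC-seq lists from 33881 to 72433. The inputs gave 253 and 424 regions, none of them inside a Hox cluster. Because lists of a mark differed in length, the main comparisons were repeated with lists of equal length. Most regions of each replicate list were shared with the other, except in the longer E7.2 list. In the first direction (the first replicate in the second), 83.6% of H3K27ac regions at 24 h, 81.8% of H3K27me3 regions, 70.2% of Ring1b regions, 78.2% of E6.0 and 96.1% of E7.2 ATAC-seq regions overlapped. In the other direction the shares were 90.3%, 52.0%, 65.5%, 72.3% and 42.7%. Regions shifted at random along the chromosomes overlapped in 0.305% to 2.73% on average.

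The first comparison asked how the 4 Hox clusters, which hold the genes that set position along the body axis, change their marks under Wnt stimulation. H3K4me3 coverage was higher at 72 h of CHIR99021 than at 12 h in each cluster in Wnt3 KO cells. At 0 h, H3K4me3 regions covered 4.04% of the clusters together, at 6 h 2.77%, at 12 h 4.27% and at 72 h 14.0%. HoxA went from 5.22% at 0 h to 19.2% at 72 h, HoxB from 3.78% to 15.2%, HoxC from 2.61% to 7.36% and HoxD from 4.96% to 14.4%. The number of H3K4me3 regions went from 7 to 21 in HoxA, from 9 (95% exact Poisson interval 4.12 to 17.1) to 28 (18.6 to 40.5) in HoxB, from 5 (1.62 to 11.7) to 14 (7.65 to 23.5) in HoxC and from 9 to 21 in HoxD. Intervals at 0 h and 72 h were apart only in HoxB and overlapped in HoxA, HoxC and HoxD, and over all 4 clusters the number went from 30 (20.2 to 42.8) to 84 (67.0 to 104.0). At 72 h, coverage of HoxA, HoxB and HoxD was at the 100th percentile of 10000 random windows of the same length, and that of HoxC at percentile 99.5. H3K4me3 regions at 72 h reached from 52105639 to 52196643 on chromosome 6 (HoxA), from 96051466 to 96228879 on chromosome 11 (HoxB), from 102751754 to 102866282 on chromosome 15 (HoxC) and from 74506353 to 74601816 on chromosome 2 (HoxD), in mm9 coordinates. There was 1 library per time point, so the change had no replicate check, and the Poisson intervals cover counting error only.

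Coverage was then compared along the clusters. Each cluster was split into 3 equal parts, and H3K4me3 coverage of the 3′ parts, 3′ being the end toward which transcription of the Hox genes runs, was 4.47% at 0 h, 4.46% at 6 h, 7.59% at 12 h and 13.5% at 72 h. The middle parts went from 4.18% at 0 h through 2.60% and 3.07% to 15.7%, and the 5′ parts from 3.47% through 1.27% and 2.13% to 12.9%. The 3′ parts exceeded the 5′ parts by 1.00 points at 0 h, 3.19 at 6 h, 5.46 at 12 h and 0.668 at 72 h. The 6 h and 12 h lists came from another processing folder of the authors than the 0 h and 72 h lists. Between the 6 h and 12 h lists of the same folder the excess grew by 2.27 points (1.51 with lists of equal length), within a counting error of 5.25 points. The step was not shared by every cluster, as in HoxD the 3′ part went from 4.34% to 4.16% and the 5′ part from 1.08% to 2.62%.

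**Figure D1:**
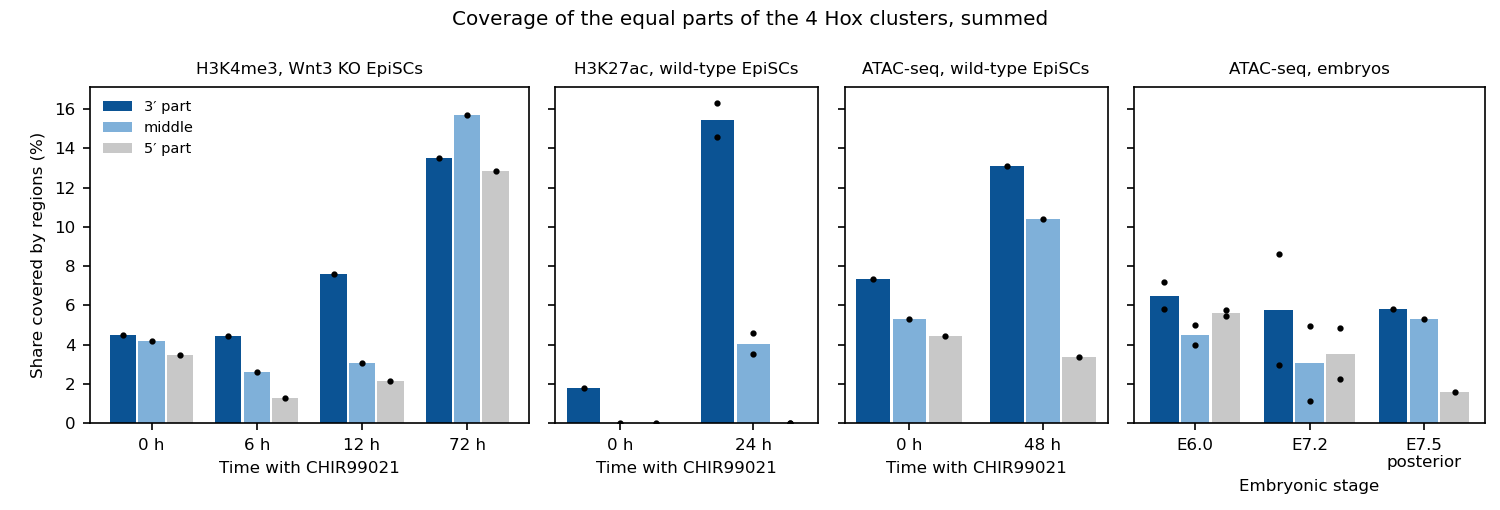
Share (%) of the summed 3′, middle and 5′ parts of the 4 Hox clusters covered by regions, for H3K4me3 against hours with CHIR99021 in Wnt3 KO EpiSCs, H3K27ac and ATAC-seq against hours in wild-type EpiSCs, and ATAC-seq against embryonic stage. Bars are means and points single libraries; at 24 h the H3K27ac coverage of the 3′ parts was 16.3% and 14.6%, with none in the 5′ parts, and ATAC-seq coverage of the 3′ parts was 13.1% at 48 h against 7.34% at 0 h.

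H3K27ac in wild-type EpiSCs rose in the Hox clusters at 24 h of CHIR99021, in the 3′ parts and in the middle. Coverage of the 4 clusters was 0.606% at 0 h (1 library) and 6.51% ± 0.656 (SD, n = 2) at 24 h, a difference of 5.90 points. HoxA had 4 H3K27ac regions at 0 h and 19 and 15 in the replicates at 24 h, and HoxB 2 at 0 h and 20 and 18 at 24 h. HoxC and HoxD had 0 at 0 h, and 6 and 4 (HoxC) and 10 and 8 (HoxD) at 24 h. At 24 h coverage of HoxA and HoxB lay at percentiles 99.8 to 99.9 of random windows. HoxD was at 96.0 and 93.5 and HoxC at only 83.9 and 76.5. Mean coverage of random windows of the HoxC length also rose, from 0.418% to 1.04% and 0.963%. The 3′ parts were covered by 16.3% and 14.6% at 24 h and by 1.82% at 0 h, the middle by 4.58% and 3.53%, and no H3K27ac region lay in the 5′ parts in any of the 3 libraries. The excess of the 3′ over the 5′ parts grew by 13.6 points, against an SD of 1.23 points between the 24 h replicates. With lists of equal length, the coverage difference was 2.18 points and the excess grew by 5.70 points. The 0 h and 24 h lists came from separate processing folders of the authors, so folder and stimulation cannot be told apart here. In Wnt3 KO cells, H3K27ac covered 0.288% of the clusters at 0 h, 0.168% at 6 h, 0.376% at 12 h and 1.21% at 72 h, when 13 regions were listed.

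Open chromatin covered more of the Hox clusters of wild-type EpiSCs at 48 h of CHIR99021 than at 0 h, with 1 library at each time. ATAC-seq regions covered 5.70% of the 4 clusters at 0 h and 8.96% at 48 h, a difference of 3.27 points. The SD between embryo libraries was 0.489 points at E6.0 and 2.85 at E7.2 (n = 2 each), and EpiSCs had no ATAC-seq replicates. HoxB went from 18 to 27 regions and HoxD from 12 to 22. Coverage of the 3′ parts was 7.34% at 0 h and 13.1% at 48 h, that of the middle 5.32% and 10.4%, and that of the 5′ parts 4.43% and 3.38%. In embryos, ATAC-seq covered 5.53% ± 0.489 (SD, n = 2) of the clusters at E6.0, 4.13% ± 2.85 (SD, n = 2) at E7.2 and 4.23% in the E7.5 posterior library. The E7.2 minus E6.0 difference of -1.40 points was smaller than the spread between the E7.2 libraries, whose lists held 33881 and 72433 regions, and it was 0.613 points without the shorter one, -3.42 points without the longer one (both tried after the results were seen) and 0.00215 points with lists of equal length. In the E7.5 posterior library the 3′ parts were covered by 5.81%, the middle by 5.32% and the 5′ parts by 1.57%. The 5′ parts were covered by 5.75% and 5.44% in the E6.0 libraries and by 2.25% and 4.83% in the E7.2 libraries. The E6.0 lists, of 57569 and 61933 regions, were longer than the E7.5 posterior list of 42338. The 0 h and 48 h EpiSC lists came from separate processing folders, so folder and stimulation cannot be told apart for the coverage itself.

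The Polycomb comparison asked whether H3K27me3 and Ring1b leave their regions under Wnt stimulation. At the Hox clusters, Ring1b covered 4.86% ± 1.51 (SD, n = 2) at 0 h, 4.62% after 5 h of Wnt3a and 0.213% after 72 h of CHIR99021, when 3 regions were left, all in HoxA. HoxA had 16 and 11 Ring1b regions in the 0 h replicates, HoxB 12 and 9, HoxC 12 and 8, and HoxD 11 and 5. The change of -4.65 points at 72 h was larger than the SD between the 0 h replicates and was -3.58 points against the 0 h library of the same folder, but the 72 h list was the shortest of the 4, and with lists of equal length the change was -1.25 points. The change of -0.237 points after Wnt3a was within that SD, and it was 0.830 points against the second 0 h replicate alone and -1.30 against the first. At equal length it was -1.08 points, so the contrast between 5 h of Wnt3a and 72 h of CHIR99021 in the clusters was small there. H3K27me3 covered 0.962% ± 0.604 (SD, n = 2) of the clusters at 0 h, 0.177% at 12 h and none at 5 h of Wnt3a or at 6 h or 72 h of CHIR99021. Against single 0 h replicates the change at 72 h was -0.534 (the first) and -1.39 points (the second). With H3K27me3 lists of equal length no region was left in the clusters at any time, so this loss was not detectable at equal length.

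Across the genome, Ring1b regions were largely listed again after 5 h of Wnt3a and mostly not listed at 72 h of CHIR99021. Of the 1126 Ring1b regions present in both 0 h replicates, 90.8% (95% Wilson interval 88.9 to 92.3) overlapped a region after 5 h of Wnt3a and 27.1% (24.6 to 29.8) at 72 h. With every Ring1b list cut to its 604 strongest regions, the 0 h lists too, the shares were 87.5% and 46.6%. These are shares of a smaller set of strong 0 h regions, so they do not correct the first shares for the short 72 h list. Of the Ring1b regions listed at 72 h, 24.8% overlapped an input region, against 16.1% and 7.40% in the 0 h replicates, and these shares do not tell a weaker library from a loss of Ring1b. Of the 3543 H3K27me3 regions in both 0 h replicates, 22.4% (21.04 to 23.78) were listed after 5 h of Wnt3a, 40.7% (39.1 to 42.3) at 6 h of CHIR99021, 44.8% (43.2 to 46.5) at 12 h and 41.5% (39.9 to 43.2) at 72 h. The Wnt3a list of H3K27me3 held only 1012 regions, of which 21.3% overlapped an input region against 5.22% and 2.76% at 0 h. With every H3K27me3 list cut to 1012 regions the share listed after Wnt3a was 58.2%, again over a smaller set of 0 h regions. Over all regions of the first and of the second 0 h replicate, the Ring1b list after Wnt3a, longer than both, held 81.4% and 71.4%, and the other replicate 70.2% and 65.5%. For H3K27me3 the Wnt3a list held 19.8% and 12.9%, and the other replicate 81.8% and 52.0%. The Ring1b regions with the highest fold enrichment, as the authors computed it, among those absent at 72 h were at 18620169 to 18621539 on chromosome 2 (15.0-fold), at 62302623 to 62304234 on chromosome 14 (14.2-fold) and at 70400251 to 70402288 on chromosome 2 (12.5-fold), leaving out a region on chromosome 16 that lay within 100 kb of an input region. For H3K27me3 they were at 18775100 to 18776880 on chromosome 11 (9.95-fold) and at 79819384 to 79820723 on chromosome 10 (9.87-fold).

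H3K27me3 regions that also carry H3K4me3, the combination called bivalent, were compared at matched times in Wnt3 KO cells. At 0 h, 35.7% (34.3 to 37.2) and 39.2% (38.04 to 40.46) of the H3K27me3 regions of the replicates overlapped H3K4me3. The share was 20.8% (19.2 to 22.4) at 6 h, 25.8% (24.3 to 27.4) at 12 h and 35.05% (33.40 to 36.73) at 72 h. Against the 0 h mean the differences were -16.7, -11.7 and -2.44 points, with an SD of 2.48 between the 0 h replicates, so only those at 6 h and 12 h exceeded it. Both 0 h replicates were set against the same H3K4me3 list, so this SD holds no variation between H3K4me3 libraries. With lists of equal length they were -32.8, -26.8 and -16.3 points, and with an overlap of at least 50% of the smaller region the first 2 were -9.24 and -4.97 points. Against a single 0 h replicate, the 72 h difference was -0.686 points for the first and -4.19 points for the second. The second replicate came from the same folder as the 72 h list, and its difference was beyond that SD, with 1 library on each side. The 6 h and 12 h lists were again from another folder than the 0 h and 72 h lists, so folder and time cannot be told apart for them. Their H3K4me3 regions were also shorter, with medians of 930 and 936 bp against 1237 bp at 0 h and 1230 bp at 72 h. Median H3K27me3 lengths were 396 and 389 bp, against 500 and 527 bp at 0 h and 400 bp at 72 h. The effect of region length on the share was not tested.

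H3K27ac regions gained and lost with CHIR99021 were counted across the genome. The wild-type 0 h and 24 h lists came from separate folders, as did the 6 h and 12 h lists of Wnt3 KO cells and their 0 h list, so only the comparison of 72 h with 0 h lies within a folder. In wild-type EpiSCs, 64.7% (95% Wilson interval 64.1 to 65.2) and 62.8% (62.2 to 63.4) of the regions in the 24 h replicates had no overlap at 0 h, and 15.6% (15.0 to 16.2) and 17.0% (16.4 to 17.6) of the 0 h regions had none at 24 h. With lists of equal length, 35.3% were gained and 24.8% lost. At full length the 24 h replicates shared 83.6% and 90.3% of their regions. The wild-type losses were therefore near the difference between libraries of 1 condition, and the gains were beyond it. At equal length the replicates shared 93.4%, and both gains and losses were beyond that difference. Of 24293 regions found in both replicates at 24 h, 14350 (59.1%) were gained. Those with the highest fold enrichment, by the authors' values, were at 18593419 to 18594849 on chromosome 2 (26.3-fold), at 53132778 to 53133705 on chromosome 5 (26.2-fold) and at 120801646 to 120803088 on chromosome 10 (25.9-fold). Of the 10 leading gained regions, 8 were already listed for H3K27ac in unstimulated Wnt3 KO cells and 9 were open by ATAC-seq at 0 h. The leading lost regions were at 65758168 to 65759573 on chromosome 15 (17.9-fold) and at 66432806 to 66434820 on chromosome 7 (17.1-fold). Of the 10 leading lost regions, 9 were open by ATAC-seq at 0 h and 2 at 48 h. In Wnt3 KO cells, 24.0% (23.2 to 24.9) of regions were gained and 40.0% (39.1 to 40.9) lost at 6 h, 25.2% (24.4 to 26.0) and 31.9% (31.1 to 32.8) at 12 h, and 17.4% (16.7 to 18.2) and 30.4% (29.6 to 31.2) at 72 h. These cells had no H3K27ac replicates, and the gain at 72 h was near the difference between the wild-type 24 h replicates. The 72 h shares were 23.5% and 24.0% with lists of equal length, but equal lengths by themselves bring gains and losses close together.

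The ATAC-seq comparison asked whether chromatin opened by CHIR99021 in EpiSCs is open in embryos. In wild-type EpiSCs, 10443 regions were open at 48 h and not at 0 h (gained), 13949 at 0 h and not at 48 h (lost), and 27589 at both times. Each time had 1 library. Embryo libraries of 1 stage shared 78.2% and 72.3% of their regions at E6.0, and 96.1% and 42.7% at E7.2. Part of the gained and lost classes may therefore be differences between libraries. In the E7.5 posterior library, 43.7% (95% Wilson interval 42.7 to 44.6) of the gained and 13.2% (12.7 to 13.8) of the lost regions were open, a difference of 30.5 points, while shifted regions overlapped in 1.42% and 1.40%. At E6.0 the lost regions were the ones more often open, at 46.9% and 53.5%, against 22.7% and 26.8% of the gained regions. At E7.2 the shares were 17.5% gained and 20.9% lost in the first library, and 50.1% gained and 52.4% lost in the second. Stages here follow the labels, which differ from the stage names inside the peak names, so their assignment is uncertain. The gained minus lost difference was -25.4 ± 1.79 points (SD, n = 2) at E6.0 and -2.81 ± 0.761 points (SD, n = 2) at E7.2. The stages differed by 22.6 points, with p = 0.333 in an exact two-sided permutation test, the smallest p that 2 against 2 libraries allow. Within the authors' processing folders, each with 1 library per stage, the difference was 20.8 and 24.4 points, and with lists of equal length it was 17.5 points. Of the 10 gained regions with the highest fold enrichment, 8 were open in the E7.5 posterior library, 4 in each E6.0 library and 6 and 10 in the E7.2 libraries. Of the 10 leading lost regions, 2 were open in the E7.5 posterior library, 10 in each E6.0 library and 5 and 9 in the E7.2 libraries. H3K27ac was listed at 3 of the 10 leading gained regions in each 24 h replicate. Examples are the regions at 93802824 to 93804219 on chromosome 15 (54.0-fold, by the authors' values) and at 71682658 to 71683905 on chromosome 9 (50.7-fold), both among these 3. The leading gained region, at 3258606 to 3258941 on chromosome 9 (175-fold), was listed at E6.0 and E7.2 as well and in no ChIP-seq library. Lost regions with the highest enrichment were at 78688592 to 78689430 on chromosome 14 (49.8-fold) and at 69484912 to 69486086 on chromosome 4 (49.2-fold), both with H3K27ac at 0 h in wild-type cells and without it at 24 h.

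**Figure D2:**
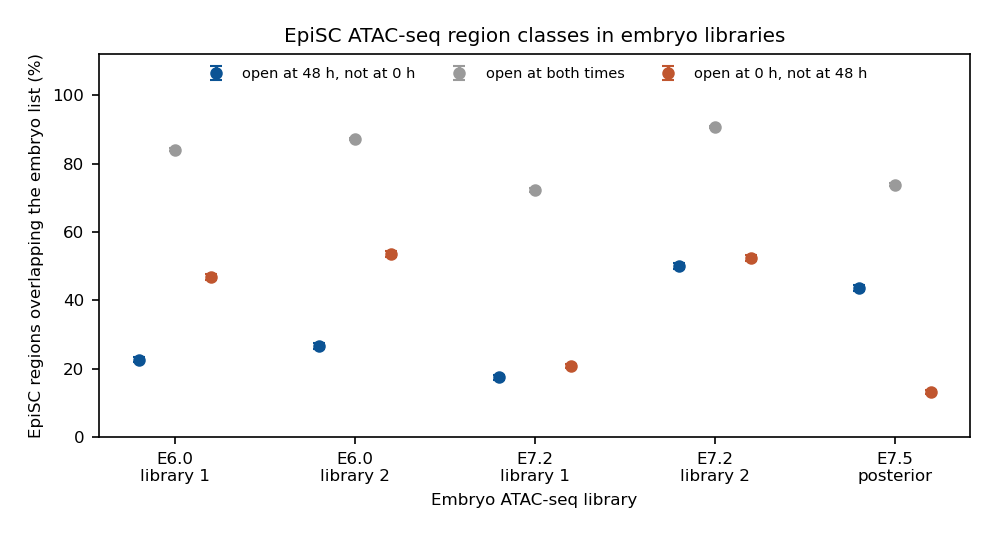
Share (%) of EpiSC ATAC-seq regions open at 48 h but not at 0 h of CHIR99021, at both times, or at 0 h but not at 48 h that overlap each embryo library (horizontal axis); points are libraries and bars, smaller than most points, 95% Wilson intervals. Gained regions exceed lost ones only in the E7.5 posterior library (43.7% against 13.2%), and at E6.0 the order is the opposite.

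H3K27ac was then set beside the same ATAC-seq classes in wild-type EpiSCs. Gained ATAC-seq regions overlapped H3K27ac in 0.958% (0.788 to 1.16) at 0 h and in 18.3% (17.6 to 19.1) and 16.3% (15.6 to 17.1) at 24 h in the replicates. Lost regions overlapped H3K27ac in 6.93% (6.52 to 7.37) at 0 h and in 9.51% (9.03 to 10.0) and 8.17% (7.73 to 8.64) at 24 h. The gained minus lost difference was therefore -5.97 points at 0 h and 8.49 points at 24 h, and it was -3.80 and 4.45 points with an overlap of at least 50% of the smaller region. With lists of equal length, an alternative added after the results were seen, it was -5.77 and 3.72 points. Regions open at both times overlapped H3K27ac in 32.7% at 0 h and in 59.0% and 57.7% at 24 h, so overlap rose in every class, with 24 h lists of 29056 and 27422 against 14453 regions at 0 h. Regions are not replicates, so the intervals describe these libraries and no p-value is given.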

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

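No test was chosen for this part after the results were seen, because none was run on these values.

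The total length covered by H3K27ac regions moved in opposite directions in the cell lines, but so did the number of regions listed. In Wnt3 KO EpiSCs the length covered by H3K27ac regions was smaller than at 0 h in each stimulated library, by a change of -2.31 Mb at 6 h, -0.956 Mb at 12 h and -1.12 Mb at 72 h, with a mean of -1.46 Mb, and the lists went from 12135 regions to 10225, 11636 and 10161. In wild-type EpiSCs it was larger at 24 h in both replicates, by 16.3 and 14.3 Mb, with a mean of 15.3 Mb, and the lists went from 14453 regions to 29056 and 27422. The difference between the lines was not tested, and covered length was not compared at equal list length. In the Hox clusters H3K27ac coverage was higher than at 0 h in both lines, at 72 h in Wnt3 KO cells (0.288% to 1.21%) and at 24 h in wild-type cells (0.606% to 6.51%). Times of sampling and processing folders also differ between the lines, and the 0 h lists come from other folders than the 24 h lists of wild-type cells and the 6 h and 12 h lists of Wnt3 KO cells, so the difference cannot be assigned to the genotype. No biological explanation was tested.

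The pair of wild-type H3K4me3 libraries with contradictory labels showed H3K4me3 in the Hox clusters, where the inputs had none. In the first, H3K4me3 regions covered 7.61% of the 4 clusters, and in the second 15.2%. In the 3′ parts they covered 10.7% in the first and 24.0% in the second, and in the 5′ parts 5.07% and 5.01%. They belong to no group here, so the values are given singly and are not compared with the time course.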

How the results depend on the processing

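The alternative without regions that overlap an input region, the crossed pairing, leaving out each embryo library for Hox coverage, and lists of equal length for H3K27ac at ATAC-seq classes were chosen after the results were seen. Of 231 values under an alternative, for 48 results, 223 kept the sign of the main value, 4 were exactly 0 (H3K27me3 in the Hox clusters at equal length) and 4 had the opposite sign. These 4 belong to differences within their spread: H3K4me3 in the Hox clusters at 12 h (-0.537 points at equal length), Ring1b there after Wnt3a (0.830 without the first 0 h replicate) and ATAC-seq there at E7.2 minus E6.0 (0.00215 at equal length and 0.613 without the first E7.2 library). Replicate overlaps, gained, lost and kept shares and the totals cannot be negative, so a kept sign says nothing about them. For the 29 main results with a spread, 91 values stayed within it and 56 moved beyond it. For the other results 54 stayed and 24 moved, 15 of them closer to 0 and 9 farther away. The total number of regions, 591931, became 511255 after merging within 1 kb, and the total length went from 433 to 464 Mb. The cause of the moves was not tested except where the alternative itself, by dropping regions, sets a list shorter. Depth is unknown, so a region absent from a short list (1012 for H3K27me3 after Wnt3a, 604 for Ring1b at 72 h) is not shown to be absent from the cells. Marks at promoters of listed genes, peaks near listed genes and motifs in gained regions were not run.

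Replicate overlap is given here for the shorter list in the longer one, which is the second in the first for H3K27ac (90.3% in the main analysis) and the first in the second for the others, and at equal length for the first in the second. With an overlap of at least 50% of the smaller region, it was 89.2% for H3K27ac, 76.3% for H3K27me3, 66.2% for Ring1b, 77.0% at E6.0 and 95.1% at E7.2. H3K27ac gains and losses at 72 h in Wnt3 KO cells were 19.4% and 32.3%, and losses in wild-type cells 18.3%. H3K27ac at gained minus lost ATAC-seq regions was -3.80 points at 0 h and 4.45 at 24 h.

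With a −log10 q of at least 5, the replicate overlap was 83.2% for H3K27me3, 79.2% at E6.0 and 97.3% at E7.2. H3K27ac gains and losses at 72 h in Wnt3 KO cells were 15.9% and 29.4%. The kept share was 15.8% for H3K27me3 after Wnt3a, 36.1% at 72 h, and 23.6% for Ring1b at 72 h.

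With lists of equal length, the replicate overlap was 93.4% for H3K27ac, 62.0% for H3K27me3, 67.5% for Ring1b, 79.2% at E6.0 and 80.4% at E7.2. The Hox coverage difference was 0 points for H3K27me3 at 72 h, -1.08 and -1.25 for Ring1b after Wnt3a and at 72 h, and 2.18 for H3K27ac in wild-type cells. The change in the excess of the 3′ over the 5′ parts was 5.70 points for H3K27ac. H3K27ac gains and losses were 23.5% and 24.0% in Wnt3 KO cells and 35.3% and 24.8% in wild-type cells. The kept share of H3K27me3 was 58.2% after Wnt3a and 44.7% at 72 h, and of Ring1b 87.5% and 46.6%, each over the 0 h regions shared by the shortened replicate lists. H3K27me3 with H3K4me3 at 72 h differed by -16.3 points from 0 h. Gained minus lost ATAC-seq regions differed by -20.8 points at E6.0 and 29.0 at E7.5, and E7.2 minus E6.0 was 17.5 points. H3K27ac at 24 h at gained minus lost ATAC-seq regions was 3.72 points.

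With Hox windows 20 kb longer on each side, Hox coverage differed by 4.85 points for H3K27ac in wild-type cells and by 2.55 for ATAC-seq in EpiSCs, and the excess of the 3′ parts changed by 10.9 and 5.13 points. Without regions that overlap an input region, the Ring1b replicate overlap was 74.8%, and the kept share was 19.3% for H3K27me3 after Wnt3a, 39.5% at 72 h and 19.9% for Ring1b at 72 h.

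Leaving out a replicate, the kept share of H3K27me3 lay between 12.9% and 19.8% after Wnt3a and between 29.8% and 36.4% at 72 h, and that of Ring1b between 71.4% and 81.4% and between 21.5% and 21.7%. These shares are over all regions of 1 replicate, which include those the other lacks.

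With the replicate block, the E7.2 minus E6.0 difference stayed at 22.6 points (exact permutation p = 0.5, the smallest for 2 pairs). With crossed numbers the pairs differed by 21.9 and 23.3 points, with the same exact p, and no call changed. Deviations of same-numbered libraries correlated at -1, which 2 groups of 2 always give as 1 or -1.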

Other observations

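All tests in this part, and the scan of tiles, were chosen after the results were seen, except the undivided test of H3K4me3 beside Ring1b, whose bound was set in advance. The bound of the test on local background, for Ring1b without H3K27me3, was tightened after its value was seen.

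Among 26397 tiles of 100 kb over the genome, the 3 with the largest gain in H3K4me3 between 0 h and 72 h in Wnt3 KO cells lay in HoxB (16.5 kb), HoxA (16.0 kb) and HoxD (9.87 kb), and the same clusters led with lists of equal length. The best HoxC tile was at rank 13, and at rank 11 with lists of equal length. The next tile, at 108700001 to 108800000 on chromosome 11, gained 6.32 kb. In ATAC-seq between 0 h and 48 h in wild-type EpiSCs, the best tiles of HoxB, HoxC, HoxD and HoxA were at ranks 1, 2, 5 and 28, and at ranks 2, 1, 5 and 22 with lists of equal length. In H3K27ac between 0 h and 24 h in wild-type cells, from lists of 14453 against 29056 and 27422 regions in separate folders, HoxA, HoxB, HoxD and HoxC reached ranks 6, 18, 449 and 538. HoxA, HoxB and HoxD were at ranks 73, 6 and 4119 with lists of equal length, and HoxC had no tile with a gain, so these ranks depend on the length of the lists. In H3K27ac of Wnt3 KO cells at 72 h no Hox tile was among the first 10, and the best, in HoxD, was at rank 12, or 19 with lists of equal length.

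Few Ring1b regions in the Hox clusters carried an H3K27me3 region at 0 h, although Ring1b and H3K27me3 went together elsewhere. Of the 19 Ring1b regions in the clusters that were in both replicates and free of input regions, 0 and 1 overlapped H3K27me3 in the replicates, against 737 (74.6%) and 891 (90.2%) of 988 such regions outside. A candidate explanation is that the authors' local background of 100 kb hides H3K27me3 where a whole neighbourhood is marked. Outside the clusters, 396 Ring1b regions in neighbourhoods as dense in Ring1b overlapped H3K27me3 less often by a difference of -3.27 points, with a spread of 4.38 points, which neither excludes nor bears out the explanation, and the density itself came from lists made with the same background. A true lack of H3K27me3 in the clusters was not tested and stays open.

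Ring1b regions in the Hox clusters were fewer at 72 h. A difference between processing folders is argued against, though weakly, as coverage changed by -3.58 points within the folder that holds both times, beyond the SD of 1.51 points. This sets 1 library against 1, and the 0 h libraries behind the SD came from different folders. With lists of equal length coverage was 1.46% at 0 h, as the mean of both folders, and 0.213% at 72 h. Whether a 72 h list that is shorter everywhere may be enough to explain it stays open: 1 of the 51 Hox regions of the first 0 h replicate was kept, as few as in 2% of sets matched on 0 h q-value, but 3 of the 33 of the second, as few as in 36.8% of such sets. Of the 51 Hox regions of the first replicate, only 19 were also listed in the second 0 h replicate, against 988 of 1295 outside. The sets were not matched on this, so the 2% does not separate a change at 72 h from regions that vary between libraries. Neighbouring regions are not independent, and why the list is shorter, by depth or by loss of Ring1b across the genome, cannot be read from 1 library.

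ATAC-seq regions gained at 48 h were more often open than lost ones in the E7.5 posterior library. With lists of equal length the difference was 29.0 points. This cut the lists only from 42338 (E7.5 posterior), 41309 (0 h) and 38032 (48 h) to 33881 regions. Both shares come from the same embryo list, so the test could hardly have gone against list length as a cause and does not decide it. A difference between processing folders is argued against, as the E7.5 posterior library, from the folder of the 0 h list, was 57.2 points above the E6.0 library from the folder of the 48 h list. The stage and the posterior position of the tissue, which the labels name together, stay open as an explanation, and they rest on 1 library. The stages are those of the labels, and the stage names inside the peak names differ from them. A hypothesis is that CHIR99021 moves EpiSCs toward chromatin like that of the posterior embryo, which these tests do not establish.

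A last hypothesis was that Ring1b loss at 72 h goes with a gain of H3K4me3 at the same region. Outside the Hox clusters, H3K4me3 within 1 kb grew by at least 200 bp at 201 of 789 lost Ring1b regions (25.5%) and at 45 of 199 kept ones (22.6%), a difference of 2.86 points, under the 5 points set in advance and with overlapping Wilson intervals, so this test does not decide. Within quintiles of 0 h q-value, a split tried afterwards, the share was higher among lost regions in 5 of 5. The Mantel-Haenszel difference was 7.92 points (95% interval 1.44 to 14.4). This interval takes regions as independent, which neighbouring regions are not, and each mark had 1 library at 72 h. It may therefore be too narrow, and the hypothesis stays open. H3K4me3 also shrank by at least 200 bp at 158 of the lost regions (20.0%) and 44 of the kept ones (22.1%) outside the clusters. In the Hox clusters H3K4me3 grew at 11 of 19 Ring1b regions (57.9%) and shrank at 1. Only 1 of these 19 regions was kept at 72 h, so lost and kept regions cannot be compared there.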
